A study of Mus musculus with 6 samples.

How the data were processed

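RNA of whole mouse digit tips was measured on Affymetrix MoGene 1.0 ST arrays, 3 arrays of control animals and 3 of animals labelled as carrying a K14-CreER-driven deletion of Ctnnb1 (called cKO here). Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates; no label says whether each came from a separate animal, so p-values measure the spread between these samples. All animals were 8 weeks old. The file headers name the whole-transcript array, while the labels' protocols name a labelling kit made for 3 prime arrays, and which kit was used was not settled here.

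Per the deposited methods sheet, the authors summarised and quantile-normalised the signals with PLIER16, took log2 values, and set each transcript cluster (the array's set of probes for a gene) to the median of the controls. The deposited log2 values are therefore relative: the control median is 0 in all 28853 clusters, no absolute level, background or detection call can be read from them, and a cluster near background cannot be told from a bright one. Subtracting a constant per cluster leaves differences between groups and their spread unaltered. The array annotation was release na31 on mouse genome build mm9, per the file headers. The authors' deposited tables also hold a signed fold score, the ratio of cKO over control with lower clusters as a negative reciprocal, and p-values with their Benjamini-Hochberg correction. Per the file headers and the methods sheet, these followed removal of entities in the bottom 20th percentile, a 1.5-fold filter and a test over the clusters left, which the header calls an unpaired t-test and the methods sheet an ANOVA. The percentile filter was rebuilt from the values: a cluster passed if all arrays of at least 1 group reached that array's 20th percentile of the control-centred values. This rule gave the deposited fold list for 2656 of 2656 clusters with at least a 1.5-fold change.

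The value table of the series was analysed; it differed from the workbook's per-array values by at most 5e-05. No column of per-array values was left without a sample. Of the clusters, 22971 carried 1 gene, 2946 several and 2936 none. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 21924 single-gene clusters were matched and 2642 symbols changed. Clusters with several genes or none were left out of the gene-level test. The plan was to represent a gene by its cluster of highest mean, but control-centred values have no level, and such a choice would select on the effect. The mean of a gene's clusters, listed beforehand as the other choice, was used instead; 1246 of 20793 genes had more than 1 cluster.

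Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 8.79), cKO minus control, with no covariate and Benjamini-Hochberg adjustment over 20793 genes at an adjusted p of 0.05. Errors given with log2 differences are limma's standard errors. Gene lists were compared with limma's camera at a preset correlation of 0.01 over lists with at least 3 measured members, adjusted over 39 lists. Alternatives to camera were an estimated correlation per list and fry, which tests whether a list's genes move one way without comparing them with other genes. The lists, the test and the rule for named genes were fixed before the data were examined. The rule names Ctnnb1; the 15 largest rises and the 15 largest falls among called genes whose groups did not overlap; up to 4 members of smallest p per list; and, where measured, Axin2, Lef1, Lgr6, Wnt10b, Fgf2, Krt14, Krt84, Krt81, Hoxc13, Msx2 and Sema5a. Fgf2 and Krt81 lie only on clusters shared with other genes and were not analysed here. The same holds for further members of several lists, and a few members were not matched. Counts of list members given below are of those measured. For lists that did not pass camera, members not called are given only where the rule names them singly, for the sex-linked list and, for the neutrophil list, in the closing section; for the other lists they are given in part. This restriction was set after the values were seen. Tables and figures were made with Python 3, pandas, numpy, scipy and matplotlib.

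On values simulated with the variances of this comparison over 20793 genes, limma recovered 22% of genes changed 2-fold and 96% of genes changed 4-fold, the plain t-test 2% of the latter, and 8.53% of the limma calls were unchanged genes. The median number of calls over 10 simulations with no change was 0. The number of arrays limits the precision, and changes near 2-fold were often missed. Alternatives were the workbook values, centring of arrays, the replicate number as a block, array weights, a plain t-test over all genes, clusters tested singly, a fold minimum, and leaving out each array. Robust variances, the authors' filters and genes with 1 cluster were added after the data were seen.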

Results

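The data comprise 6 arrays of whole, intact digit tips from 8-week-old mice, 3 labelled wild-type control and 3 labelled K14-CreER;Ctnnb1 cKO. Ctnnb1 encodes beta-catenin, a component of adherens junctions and the transducer of canonical Wnt signals. K14-CreER is a Cre recombinase, active after an inducer, under the promoter of keratin 14, which is expressed in basal epithelium such as that of epidermis and nail. A digit tip also holds dermis, bone, vessels, nerve and glands, so each value is an average over tissues of which the epithelium is the one targeted. Values are log2 signals relative to the control median of each gene, and differences are cKO minus control over 3 arrays per group. Array medians lay between -0.0086 and 0.0779. The comparison asks which transcripts differ in digit tips labelled as carrying the K14-CreER-driven deletion of Ctnnb1.

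Ctnnb1 itself was lower in the cKO, by a log2 difference of -1.14 ± 0.24 (limma SE), with values of 0, -0.19 and 0.59 in the controls and -1.10, -0.87 and -1.06 in the cKO arrays. The geometric mean was 45.3% of the control's. Its single cluster covers positions 120842593 to 120869625 of build mm9 (the chromosome is not given in the sources used here), and which of its probes lie in the deleted part was not known, so it is a limited check of the labels. The limma adjusted p was 0.0285 over all genes. The call ended without control replicate 1 (adjusted p = 0.0795), control replicate 3 (0.138), cKO replicate 1 (0.0944) or cKO replicate 3 (0.148), and under a plain t-test over all genes (0.258), while the difference stayed between -1.31 and -0.91 when 1 array was left out.

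Antimicrobial and cornified-envelope genes were among the largest rises. Defb3, a beta-defensin, was higher by 6.11 ± 0.36, S100a8 and S100a9, which form the antimicrobial protein calprotectin, by 5.05 ± 0.21 and 4.89 ± 0.23, and Lcn2, an iron-sequestering lipocalin, by 4.09 ± 0.32. The acute-phase genes Saa3 and Saa2 were higher by 5.59 ± 0.37 and 5.39 ± 0.26. Among cornified-envelope genes, Sprr2i, Sprr2e, Sprr2f and Sprr2g were higher by 5.66, 5.55, 4.49 and 4.32, and Lce3a by 4.71. Chil1, a chitinase-like protein, was higher by 4.17, Serpinb3d, a protease inhibitor, by 4.11, Csn1s1, a casein, by 4.53, and Cd3g, a subunit of the T cell receptor complex, by 4.0. The limma adjusted p of these 15 genes lay between 8.86e-08 and 2.7e-05. Every cKO array lay above every control array in each, as the naming rule required. Sprr2, Lce3, Saa and Serpinb3 genes have near-identical relatives, so the share of each member is uncertain. In all, limma called 258 genes higher and 145 lower, each by at least 1.5-fold, 66 and 35 of them by at least 4-fold. Groups did not overlap in 4032 genes (19.4%, against 10% by chance for 3 against 3). Without cKO replicate 3 the counts were 133 and 59, the lower count was 75 without control replicate 1 and 81 without control replicate 3, array weights gave 523 and 305, and a plain t-test over all genes called 10 and 3.

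**Figure D1:**
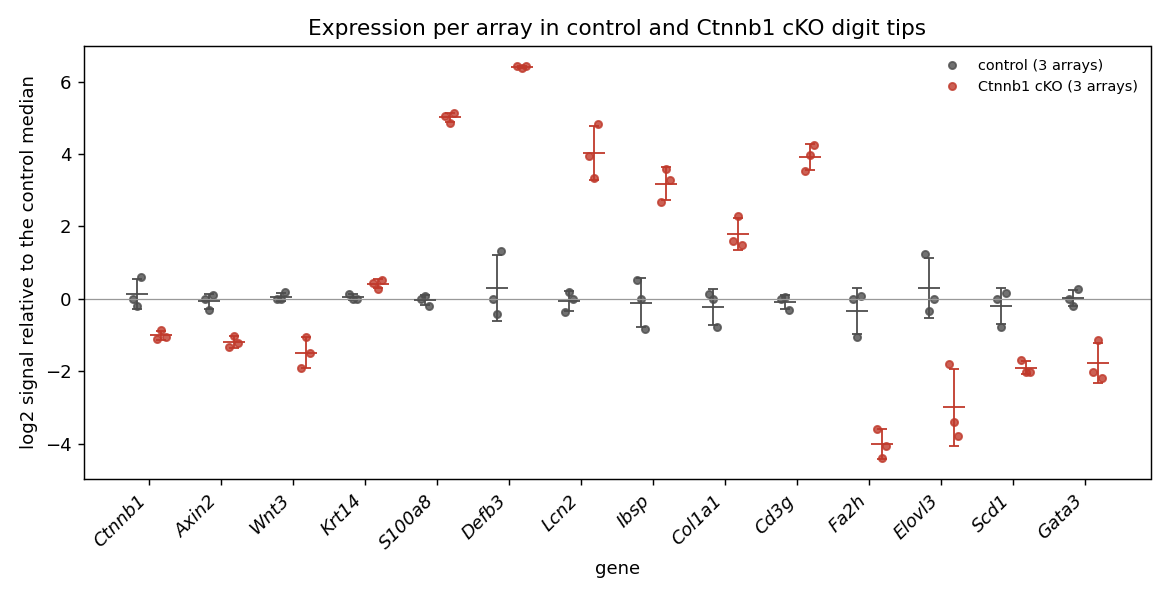
Each point is the log2 signal of 1 array relative to the control median of the gene named on the horizontal axis, in 3 control (grey) and 3 cKO (red) arrays, with horizontal bars at the group mean and error bars of 1 SD. S100a8 and Defb3 lie above 4 and Fa2h below -3 in the 3 cKO arrays, while Krt14, which was not called, lies between -0.006 and 0.52 on all 6 arrays.

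Genes of wounded or stressed epidermis, a list of keratins, small proline-rich proteins, late cornified-envelope proteins, antimicrobial peptides and cytokines, rose as a group. Of 34 measured members 26 were higher and 8 did not pass (30 higher when adjusted over the list alone), with a median of 1.90. Sprr2d was higher by 3.73 ± 0.21, in addition to S100a8, S100a9 and Sprr2i. The camera adjusted p was 3.53e-57, and adjusted p = 0.0871 with an estimated correlation. In the neutrophil list, which shares S100a8 and S100a9 with it, those were the 2 called members of 16 (also 2 adjusted over the list alone). Its median was -0.06, while its mean was 0.61 and its test pointed up, with a camera adjusted p of 0.0793 that passed without control replicate 1 (0.0373), without cKO replicate 1 (0.0472) and with fry (0.0369).

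Genes of lipid metabolism were among the largest falls. Far2, a fatty acyl-CoA reductase, fell by 5.23 ± 0.65, Fa2h, a fatty acid 2-hydroxylase, fell by 3.69 ± 0.32, Elovl3, a fatty acid elongase, fell by 3.31 ± 0.48, and Alox12e, a lipoxygenase, fell by 3.13 ± 0.26. Cd36, a fatty acid transporter, differed by -2.81 ± 0.44 and Hsd3b6, a steroid dehydrogenase, by -2.68 ± 0.60. The others of the 15 largest falls were the serpins Serpinb6d (-5.10) and Serpina3b (-4.12), Myoc (-3.86), Nhlh1, a helix-loop-helix factor (-3.84), 1110057P08Rik (-3.77), Rnase12 (-3.37), Cytl1 (-3.21), Scgb1a1, a secretoglobin (-2.78), and Egfl6 (-2.74). The limma adjusted p of the 15 lay between 1.25e-05 and 0.0392, with every cKO array below every control array, as the naming rule required. Calls ended without control replicate 1 for Cd36 (0.0763), Egfl6 (0.0881) and Hsd3b6 (0.215), without cKO replicate 3 for Egfl6 (0.0515) and Hsd3b6 (0.272), and for Hsd3b6 also without control replicate 3 (0.136) or cKO replicate 1 (0.0633). With robust variances Far2 (0.144), Elovl3 (0.0777), Cd36 (0.058), Egfl6 (0.089) and Hsd3b6 (0.368) were not called, and Hsd3b6 was not called with array weights (0.111) or centred arrays (0.0512).

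The sebaceous gland list fell: 6 of 10 members were lower and 4 did not pass (8 lower adjusted over the list alone), with a median of -1.95. Beside Fa2h and Elovl3, Scd1, a stearoyl-CoA desaturase, fell by 1.70 ± 0.26 and Mc5r, a melanocortin receptor, fell by 2.27 ± 0.36. The camera adjusted p was 2.83e-13, and adjusted p = 0.183 with an estimated correlation. The list's median was 0, -0.90 and 0.03 on the control arrays and -1.74, -2.46 and -2.52 on the cKO arrays, nearest to the controls in cKO replicate 1, which also stood apart in sex-linked genes. Its mean was -1.80, and -1.96 without that array. The call of Mc5r ended without control replicate 1 (0.0574) or cKO replicate 3 (0.0647). Keratin-associated proteins, structural proteins of hair and nail, shifted down, with 3 of 43 lower (11 adjusted over the list alone) and a median of -0.35. The 3 were Krtap17-1 (-1.99), Krtap24-1 (-2.30) and Krtap26-1 (-1.81). The median of the keratin-associated list was -0.70, -0.14 and -0.47 on the cKO arrays. Its mean was -0.58, but -0.39 without cKO replicate 1 and -0.82 without cKO replicate 2. Krtap4-2 differed by -1.72 with an adjusted p of 0.0503, and was called with array weights (0.0106), after the authors' percentile filter (0.0379), among genes with 1 cluster (0.0352), without cKO replicate 2 (0.0219) and, at -1.09, without cKO replicate 1 (0.0492). The list's camera adjusted p was 5e-09, with adjusted p = 0.437 with an estimated correlation and 0.256 with fry. The calls of Krtap17-1, Krtap24-1 and Krtap26-1 ended without control replicate 1 (0.0578, 0.0945 and 0.145) and without cKO replicate 3 (0.052, 0.173 and 0.169), that of Krtap26-1 without cKO replicate 1 (0.0671), and with robust variances those of Krtap24-1 (0.126) and Krtap26-1 (0.0596).

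In the nail and hair matrix list, Gata3, a transcription factor, fell by 1.80 ± 0.28 and S100a3 fell by 1.23 ± 0.29, the desmosomal cadherin Dsc2 rose by 1.30 ± 0.24, and 30 of 33 did not pass (5 lower and 1 higher adjusted over the list alone). That list's camera adjusted p was 0.00829, with adjusted p = 0.183 with an estimated correlation, 0.0543 without control replicate 3 and 0.0994 with fry. In the suprabasal epidermis list, Lce1m fell by 2.08 ± 0.25, Ivl (involucrin) fell by 1.68 ± 0.31 and Flg2 fell by 1.23 ± 0.27, Rptn (repetin) rose by 1.86 ± 0.26, and 24 of 28 did not pass (4 lower and 3 higher adjusted over the list alone). Its camera adjusted p was 0.00934, with adjusted p = 0.639 with an estimated correlation and 0.256 with fry, and it did not pass without control replicate 2 (0.0957), control replicate 3 (0.065) or cKO replicate 1 (0.0696). Circadian clock genes shifted down, with Hlf (-1.06) and Arntl (-1.17) lower of 11 (2 adjusted over the list alone), camera adjusted p 0.0102, and adjusted p = 0.236 with an estimated correlation and 0.0735 with fry. Without cKO replicate 3 the calls of S100a3 (0.256), Dsc2 (0.0855), Ivl (0.0725), Flg2 (0.205), Hlf (0.0811) and Arntl (0.15) ended, and without control replicate 3 those of S100a3 (0.128), Dsc2 (0.0608), Ivl (0.0549), Flg2 (0.148), Hlf (0.056) and Arntl (0.113). Without control replicate 1 S100a3 (0.146), Ivl (0.0549) and Hlf (0.051) were not called, without control replicate 2 S100a3 (0.0905), Flg2 (0.0696) and Arntl (0.0721), without cKO replicate 1 S100a3 (0.175), Flg2 (0.111) and Arntl (0.0662), and with centred arrays S100a3 (0.0561).

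Bone genes rose. Of 17 osteoblast and osteocyte genes 8 were higher and 9 did not pass (13 higher adjusted over the list alone), with a median of 1.07. Ibsp (bone sialoprotein) was higher by 3.29 ± 0.33, Ifitm5 by 2.54 ± 0.27, and the type I collagen genes Col1a1 and Col1a2, which fibroblasts also express, by 2.01 ± 0.29 and 1.71 ± 0.27. The camera adjusted p was 1.53e-15, and adjusted p = 0.183 with an estimated correlation. In the osteoclast list Atp6v0d2, a proton pump subunit, rose by 2.85 ± 0.37, Ctsk (cathepsin K) by 2.22 ± 0.30 and Mmp9 by 3.01 ± 0.43, and 10 of 13 did not pass (4 higher adjusted over the list alone). Its median was 0.32 and its camera adjusted p 0.00312, with adjusted p = 0.437 with an estimated correlation and 0.181 with fry. Mmp9 had an adjusted p of 0.051 without control replicate 1. The cartilage list did not pass (median -0.15), with Col11a1 higher by 2.06 ± 0.28 and Chad lower (-2.34 ± 0.50) of 15 (1 higher and 2 lower adjusted over the list alone). The call of Chad ended without control replicate 1 (0.179), control replicate 3 (0.0881), cKO replicate 2 (0.0817) or cKO replicate 3 (0.223), with array weights (0.116) and with robust variances (0.26).

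Genes of T lymphocytes and natural killer cells shifted up. Cd3g, Cd3d (1.65 ± 0.27) and Il2rb, an interleukin receptor subunit (1.27 ± 0.22), rose and 11 of 14 members did not pass, among them Cd3e, chosen after its values were seen, with a difference of 0.32 ± 0.24 (4 higher adjusted over the list alone). The list's camera adjusted p was 3.49e-05, and adjusted p = 0.183 with an estimated correlation. Of 18 macrophage and dendritic cell genes, Ccr2, a chemokine receptor (1.63 ± 0.25), and Lyz2, a lysozyme (1.27 ± 0.24), rose (3 adjusted over the list alone). That list's camera adjusted p was 0.00961, with adjusted p = 0.584 with an estimated correlation and 0.352 with fry, and it did not pass without control replicate 2 (0.0731) or control replicate 3 (0.0572). Of 15 dermal fibroblast genes the matrix genes Col3a1 (1.41 ± 0.25), Col6a3 (1.46 ± 0.32) and Fbln2 (1.20 ± 0.28) rose (4 adjusted over the list alone), with a camera adjusted p of 3.88e-05, and adjusted p = 0.437 with an estimated correlation and 0.181 with fry. Calls ended without cKO replicate 3 for Lyz2 (0.1), Col3a1 (0.0693), Col6a3 (0.245) and Fbln2 (0.24), and without control replicate 3 for Lyz2 (0.0649), Col6a3 (0.112) and Fbln2 (0.193). They also ended without control replicate 1 for Col6a3 (0.104), without control replicate 2 for Fbln2 (0.0939), without cKO replicate 1 for Col6a3 (0.0656) and Fbln2 (0.0918), and with centred arrays for Fbln2 (0.0514).

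Endothelial genes shifted up by a median of 0.56. Pecam1 differed by 0.78 ± 0.24, Emcn by 0.90 ± 0.29, Egfl7 by 0.68 ± 0.23 and Kdr by 0.62 ± 0.23. Limma called 0 of the 13 (0 adjusted over the list alone, 6 at an unadjusted p under 0.05). The list's camera adjusted p was 0.000257, with adjusted p = 0.437 with an estimated correlation and 0.181 with fry. With array weights Pecam1 (0.0471) and Kdr (0.0329) were called. Genes of adherens junctions and desmosomes shifted up by a median of 0.22, with Dsc2 as the 1 called of 20 (3 adjusted over the list alone), and Cdh2, N-cadherin, differed by 1.20 ± 0.31 with an adjusted p of 0.0747. That list's camera adjusted p was 0.0232, with adjusted p = 0.245 with an estimated correlation, and it did not pass without control replicate 1 (0.129), without cKO replicate 2 (0.0597) or with array weights (0.0948). Cdh2 was called without control replicate 2 (0.0163) or cKO replicate 1 (0.0487). Dsg4, of the same list, went the other way, by -0.72 ± 0.30 (limma adjusted p 0.331), and was called at -1.09 without cKO replicate 2 (0.0455).

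Among Wnt target genes, Tnfrsf19, a tumour necrosis factor receptor family member, fell by 1.30 ± 0.21, Axin2, a feedback inhibitor of Wnt signalling, fell by 1.12 ± 0.22 and Nkd1, another inhibitor, fell by 1.49 ± 0.29, and 22 of 25 targets did not pass (5 lower and 3 higher adjusted over the list alone, 9 at an unadjusted p under 0.05). The list did not pass camera (adjusted p 0.116, median -0.10), but did without cKO replicate 3 (0.0465). Axin2 had a limma adjusted p of 0.0163, against 0.0633 without control replicate 1, 0.0866 without control replicate 3, 0.0764 without cKO replicate 1 and 0.0841 without cKO replicate 3. Nkd1 was not called without control replicate 1 (0.11), cKO replicate 1 (0.0589) or cKO replicate 3 (0.129). Lef1 differed by -0.27 ± 0.26 and Lgr6 by -0.63 ± 0.23, neither called. With array weights the log2 difference of Lef1 was 0.0058 (limma adjusted p 0.992). Of 29 Wnt ligands, receptors and secretion genes Wnt3 fell by 1.55 ± 0.24 and was the 1 called (also 1 adjusted over the list alone), and Wnt10b differed by 0.44 ± 0.27. That list's median was 0.03 while its mean was -0.04 and its test pointed down, with a camera adjusted p of 0.841.

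Krt84, a nail and hair keratin, differed by 0.88 ± 0.23 with an adjusted p of 0.0879 and was called with array weights (0.0107). In the hard keratin list limma called 0 of 9 (1 higher and 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05). It was fixed with 14 members, of which 3 lay only on clusters shared with other genes and 2 were not matched. Krt85 is among those not analysed. That list's test pointed down (median -0.24, mean -0.16), with a camera adjusted p of 0.426, but 0.0283 without cKO replicate 2 (mean -0.38). Without cKO replicate 1 the mean was 0.009. Krt14 (0.37 ± 0.20), Hoxc13 (-0.55 ± 0.22), Msx2 (-0.46 ± 0.26) and Sema5a (-0.20 ± 0.23) were not called. Krt15, a basal keratin, fell by 1.45 ± 0.23 and was the 1 called of 14 basal epidermal genes (also 1 adjusted over the list alone), a list with a median of -0.06 and a camera adjusted p of 0.573. Of 21 cell proliferation genes limma called 0 (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with a camera adjusted p of 0.564.

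Single members of further lists were called while the lists did not pass camera. Hhip, a hedgehog-binding inhibitor, fell by 2.16 ± 0.35, Slit2, an axon guidance ligand, fell by 1.07 ± 0.22, Atoh1, a Merkel cell transcription factor, fell by 1.0 ± 0.22, Irf7, an interferon regulatory factor, fell by 0.94 ± 0.22 and Elovl6, a fatty acid elongase, fell by 1.49 ± 0.25, while Fabp4, a fatty acid-binding protein, rose by 1.20 ± 0.23. Hhip was the 1 called of 22 hedgehog and Notch genes (1 adjusted over the list alone), Slit2 of 28 axon guidance genes (5 lower and 3 higher), Atoh1 of 7 Merkel cell genes (1) and Irf7 of 18 interferon response genes (2 lower). With Elovl6, Elovl3 and Scd1 made up the 3 called of 22 lipid and barrier genes (3 lower and 1 higher adjusted over the list alone), and Fabp4 and Scd1 the 2 of 14 adipocyte genes (3 higher and 2 lower). Camera passed the interferon list without control replicate 3 (0.0272) and without cKO replicate 2 (0.0437), the axon guidance list (0.0391) and the lipid list (0.0436) without cKO replicate 2, the Schwann cell list without control replicate 3 (0.0243) and the smooth muscle and pericyte list without cKO replicate 3 (0.0258). Without cKO replicate 3 the calls of Hhip (0.0693), Slit2 (0.123), Atoh1 (0.14), Irf7 (0.165), Elovl6 (0.0611) and Fabp4 (0.0612) ended, and without control replicate 1 those of Hhip (0.0578), Slit2 (0.0682), Irf7 (0.0591) and Elovl6 (0.0558). Without control replicate 2 Slit2 (0.0926), Atoh1 (0.117), Irf7 (0.114) and Fabp4 (0.0561) were not called, without control replicate 3 Atoh1 (0.164) and Irf7 (0.229), without cKO replicate 1 Slit2 (0.0784), Atoh1 (0.166) and Irf7 (0.199), and without cKO replicate 2 Atoh1 (0.05001) and Irf7 (0.0718).

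**Figure D2:**
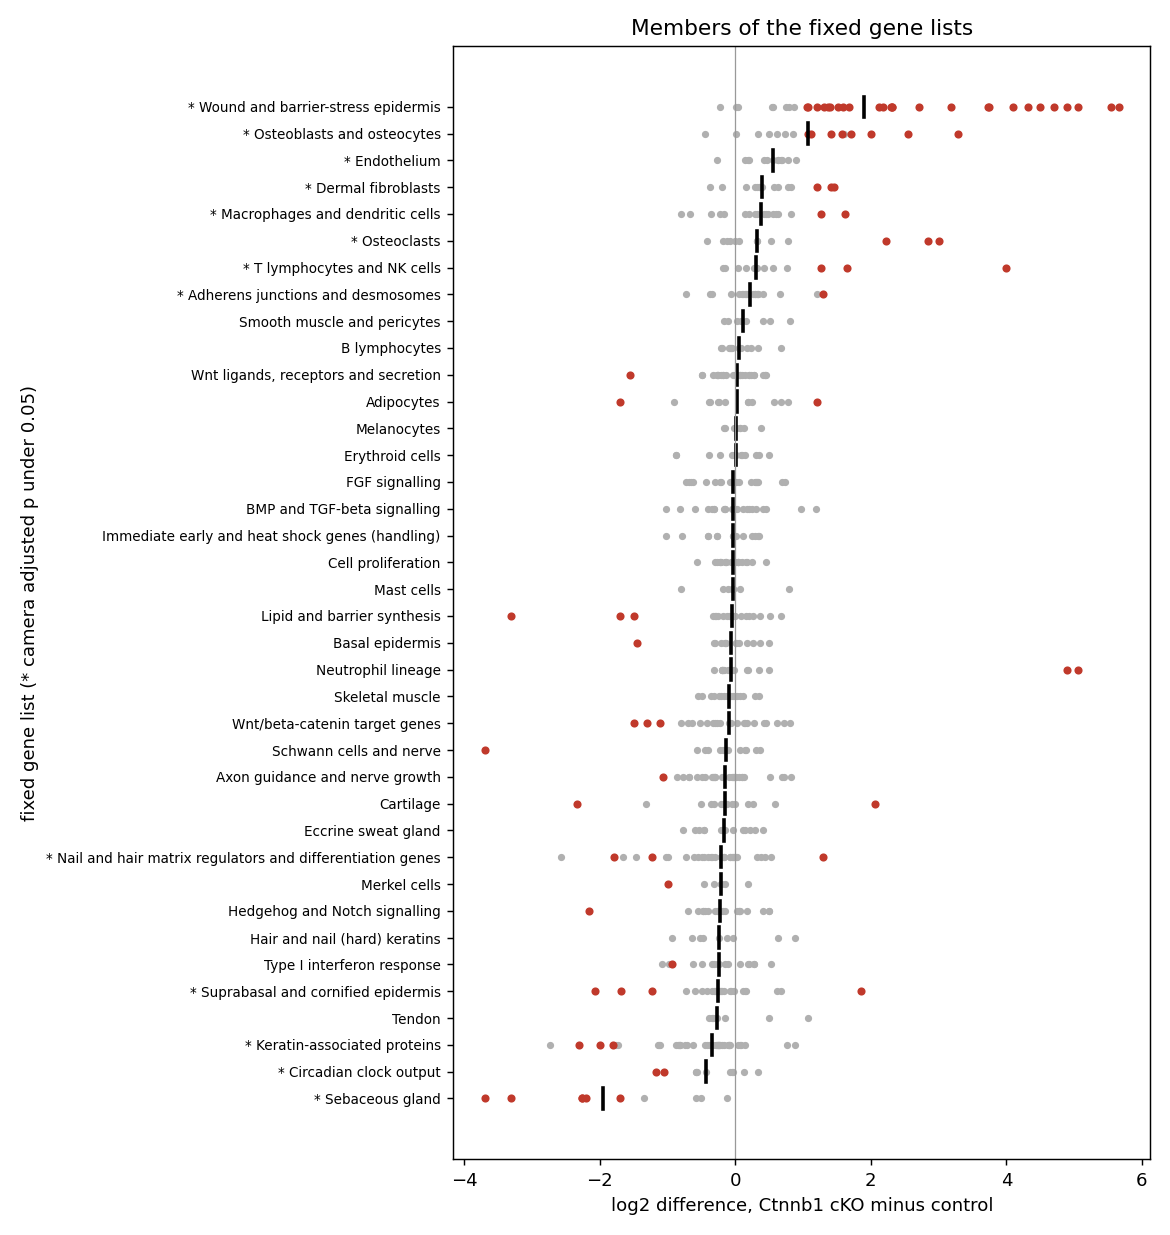
Each line of points is a fixed gene list other than the sex-linked one, and each point is the log2 difference, cKO minus control, of 1 member (red, limma adjusted p under 0.05; grey, not called), with a black bar at the list's median. The wound and barrier-stress list has its median at 1.90 and the sebaceous gland list at -1.95, and stars mark the 13 lists past camera with the preset correlation.

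Camera passed 13 of 39 lists, 8 higher and 5 lower. With an estimated correlation 0 passed (7 at an unadjusted p under 0.05), and fry passed 6. The estimated correlation in the 13 lists ran from -0.0167 (circadian clock) to 0.48 (dermal fibroblasts), against the preset 0.01. The sex-linked list showed that cKO replicate 1 stood apart: Xist, transcribed from the inactive X chromosome, was -5.84 there and between -0.39 and 0.08 on the other arrays, and the Y-linked gene Ddx3y was 8.08 against at most 0.0088. Without that array 209 genes were higher and 110 lower.

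The authors' deposited table of significant clusters lists 537 higher and 144 lower. Both counts were obtained again with their fold filter, percentile filter and t-test. With the fold filter but not the percentile filter, the t-test gave 445 higher and 260 lower clusters. Adjusted over all clusters, with neither filter, it passed 3 higher and 0 lower, so the larger counts rest on adjustment after selection by fold. The percentile filter kept 98.8% of the 1412 clusters that were at least 1.5-fold higher and 28.9% of the 1244 that were lower. Of the 145 genes called lower here, 108 were removed by it, Ctnnb1, Axin2, Far2, Fa2h and Elovl3 among them, and 31 were in the deposited list. Of the 258 called higher, 224 were in the deposited list and the filter removed 0. Seen from the deposited list, its single-gene clusters name 578 genes, 454 higher and 124 lower. Of these, 224 and 31 were called here, so many of its genes were not. In the authors' deposited table Defb3 had a fold of 69.1 and Wnt3 one of -2.93, and Krt84, not called here, a corrected p of 0.0433.

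**Figure D3:**
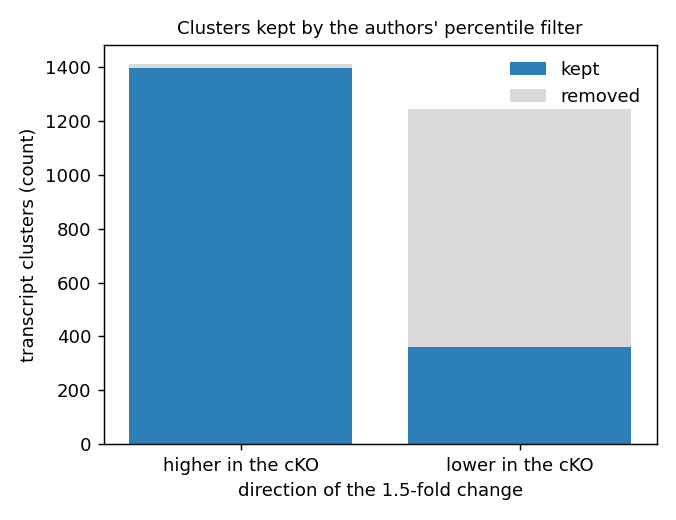
Bars count transcript clusters that differed at least 1.5-fold, by direction on the horizontal axis, stacked as kept (blue) or removed (grey) by the authors' percentile filter. The filter removed 17 higher and 884 lower clusters.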

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

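The tests of explanations in this part, the splits of the arrays among them, were chosen after the results were seen, while the limma calls, the fit of all clusters and the fits without 1 array were fixed beforehand. Signal also lay in clusters that the gene-level comparison left out: of those with several gene names, 30 of 2946 were higher and 5 lower in the cKO in limma's fit of all clusters. Of those with no gene name, 3 of 2936 were higher and 5 lower. Over all 28853 clusters, 261 were higher and 136 lower.

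The deposited list of significant clusters holds far more rises than falls. The percentile filter kept 28.94% of the 1.5-fold lower clusters against 98.8% of the higher ones, as would follow from a low-signal filter applied to values already set to the control median, where a low value is a fall. An excess of rises was also there without that filter: 64.02% of the limma calls were higher, and between 59.06% and 71.26% without 1 array. Under the authors' t-test after the 1.5-fold filter, 78.85% of the significant clusters were higher with the percentile filter and 63.12% without it. Of all clusters changed 1.5-fold, 1412 were higher and 1244 lower. The imbalance was thus smaller without the percentile filter but still there, and no cause was tested for the rest.

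The rise of wound and barrier-stress genes was weighed against cells and arrays that could bring it. Against 1 array as the cause, the list's median stayed between 1.66 and 1.93 without 1 array. Of the 18 keratin, Sprr and Lce members 14 were called higher, with a median of 1.7866 (quartiles 1.0675 and 4.1761). Neutrophils are not known to carry these epidermal genes, which argues against neutrophil RNA as the direct source of their rise. That rests on where the genes are expressed and is no separate test, since the values are those of the rise itself. An effect of neutrophils on the epidermis was not tested. For S100a8, S100a9 and the other members neutrophils stay open: the other 14 neutrophil markers had a median of -0.0938 (quartiles -0.1865 and 0.1219), with Ltf at 0.49 and Ly6g at 0.35, but no level is known and these could lie near background. The genotype, and anything else that differed between the groups, such as the inducer, remain open and untested.

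Sebaceous gland genes fell (mean -1.80, and -1.96 without cKO replicate 1, which stood apart in sex-linked genes) while bone genes rose, which a different share of tissues in the samples could bring. Markers of basal epidermis, the tissue that K14-CreER targets, did not fall with them. Their median was -0.0611 (quartiles -0.1992 and 0.1429) beside -1.95 for the sebaceous list. That argues against a loss of skin as large as the sebaceous fall only under 2 conditions. These markers must lie well above background, and their expression within the targeted epidermis must be unaltered. Neither is known. A lower share of skin should raise tissues outside skin alike. The 181 markers of 14 cell types outside epithelium and bone had a median of 0.0782 (upper quartile 0.4261). The osteoblast list had a median of 1.07 (lower quartile 0.62). Skin also holds some of those 14 types, such as Schwann cells (median -0.13), macrophages (0.38), dermal fibroblasts (0.39) and endothelium (0.56). The pooled median therefore cannot decide the question. Lists of tissues beneath the skin did not share the bone rise in their medians: tendon -0.27, cartilage -0.15 and skeletal muscle -0.09. Their levels are unknown and could lie near background, so a lower share of skin stays open for the bone genes. Changes in the lists that rose stay open too. Less haired skin in the cKO samples cannot be told apart from a loss of gland and hair transcripts in the skin itself, since keratin-associated genes had a median of -0.3465 (lower quartile -0.8342) and both would lower them. The genotype, and more bone in the samples against higher expression in bone, were not tested.

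Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 403 genes and the highest other 1, and 1 split, the real one, gave as many. For lists past camera the real split gave 13 and the others between 3 and 9, again 1 split with as many. Camera at the preset correlation passed lists in every other split, where limma called at most 1 gene. Each other split mixed the groups unevenly, so part of the real difference stayed in it and the rest widened the spread. These splits therefore cannot show how many genes or lists would pass with no difference. With 10 splits no share under 0.1 can be reached.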

How the results depend on the processing

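Robust variances, the authors' filters and the restriction to genes with 1 cluster were chosen after the data were seen. Values without a level left several alternatives not run: renewed quantile normalisation, a filter on mean level, detection calls, pseudocounts, a variance trend and the cluster of highest mean; signal over background is unknown for the same reason. Workbook values gave the same 258 higher and 145 lower genes, and array centring (231 and 139), a 1.5-fold minimum, robust variances (272 and 136), clusters tested singly and genes with 1 cluster kept both counts within 1.5 times. A plain t-test over all genes called 10 and 3, and Ctnnb1, at -1.14, was not called; each gene's spread then rests on its own arrays. Array weights called 523 and 305. Limma after the authors' percentile filter called 310 higher and 48 lower genes (86.6% higher), the authors' filters with their t-test gave 537 higher clusters, and without the percentile filter 445 higher and 260 lower. With an estimated correlation 0 lists passed and with fry 6, of which 5 were shared. Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered arrays correlated at 0.04, 0.14 and -0.09. cKO replicates 1 and 2 correlated best with the control of their own number, and cKO replicate 3 did not. With 3 arrays per group such correlations cannot exclude a pairing. With the replicate block 357 genes were higher and 218 lower, 14 lists passed, the tendon mean, at 0.0127, had the other test direction, and Krtap4-2 (0.00191), Cdh2 (0.00591), Lhx2 (0.0341) and the neutrophil list (0.0459) were called. Without 1 array, higher genes numbered 133 to 261, lower genes 59 to 165, lists 11 to 16, and Ctnnb1 lay between -1.31 and -0.91; fewer samples are part of any loss. Among 96 other named genes, calls ended for 25 without cKO replicate 3, 19 without control replicate 1, 14 without control replicate 3, 12 without cKO replicate 1, 8 without control replicate 2 and 3 without cKO replicate 2. With array weights the log2 difference of Lef1 turned to 0.0058. Lists whose test changed direction had not passed camera, and the cause was not tested. With array weights their means were 0.0059 for Wnt ligands and receptors, 0.093 for BMP and TGF-beta, 0.0179 for cartilage and 0.045 for immediate early genes. Without 1 array they ranged from -0.1408 to 0.1678 for adipocytes, -0.0729 to 0.0791 for BMP and TGF-beta, -0.2898 to 0.0172 for cartilage, -0.1478 to 0.097 for proliferation, -0.1759 to -0.0114 for erythroid cells, -0.3354 to -0.16 for lipid synthesis, -0.1904 to 0.1363 for mast cells, -0.0531 to 0.1622 for melanocytes, -0.1148 to 2.0036 for sex-linked genes, -0.1808 to 0.2233 for tendon and -0.091 to 0.0324 for Wnt ligands and receptors.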

Other observations

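Terms of the deposited gene annotation were tested for enrichment among called genes after the data were seen, with a one-sided hypergeometric test over 16648 tested genes that carry a term and 362 terms of 10 to 500 genes; genes are not independent replicates. Among higher genes 12 terms passed at a Benjamini-Hochberg adjusted p under 0.05. Besides keratinization (9 of 25 genes, adjusted p 2.98e-09), they included defense response to bacterium (9 of 50, adjusted p 9.38e-07), with the peptidoglycan recognition genes Pglyrp3 and Pglyrp4 beside defensins. The keratinization genes include the near-identical relatives Sprr2d, Sprr2e, Sprr2f, Sprr2g, Sprr2i and Sprr2k. These were also all 6 called genes of the passing terms keratinocyte differentiation and epidermis development, so they are not separate evidence. Proteolysis also passed (18 of 340, adjusted p 1.32e-05), with the transmembrane serine proteases Tmprss11a, Tmprss11b, Tmprss11d and Tmprss11g and the collagenase Mmp13. Inflammatory response passed with 8 of 85 genes (adjusted p 0.000534), among them the chemokines Cxcl5 and Ccl20 and the cytokine Il17f. Among lower genes 4 terms passed, each of lipid or fatty acid metabolism; the strongest, lipid metabolic process, held 10 of 181 genes (adjusted p 0.000101), with the wax synthase Awat1 and Apoe. Members named here were chosen after their values were seen.

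The array of cKO replicate 1 had the pattern of a male sample, and the other 5 arrays that of female samples. Xist, transcribed from the inactive X chromosome, was -5.84 there, while the Y-linked genes Ddx3y, Eif2s3y and Uty were 8.08, 7.62 and 6.84. On the other 5 arrays these Y-linked genes lay between -0.22 and 0.84. The labels used here give no sex. By this pattern sex was not balanced between the groups, and the main fit held no term for it.

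The subunits of the T cell receptor complex did not move alike: Cd3g differed by 4.0 ± 0.24, Cd3d by 1.65 ± 0.27 and Cd3e by 0.32 ± 0.24, and the difference between them was not tested. The sebaceous list shares Fa2h with the Schwann cell list, Elovl3 and Scd1 with the lipid and barrier synthesis list, and Scd1 with the adipocyte list. The erythroid, adipocyte and tendon lists had medians of 0.01, 0.02 and -0.27 and means of -0.07, -0.01 and 0.01, with camera pointing down, up and up and adjusted p of 0.931 in each.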
